A study of Arabidopsis thaliana with 15 samples.

How the data were processed

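Per the labels' protocols, stranded mRNA libraries were made from whole seedlings and sequenced as single reads, and the 3 biological replicates of a condition were pooled for sequencing, so condition and sequencing pool coincide. Per the submitters' processing notes, TopHat2 2.0.8, Cufflinks 2.1.1, Cuffdiff and DESeq2 and the genome build TAIR10 were used; their roles and order, the counter and its strand setting are not given in the sources used here. The authors deposited read counts per gene, unnormalized, and FPKM values per gene, both with 1 column per condition per the file headers. How replicates were combined and how the 22526 rows were chosen is not given in the sources used here. Among 13625 genes with at least 1000 reads in every column, FPKM per read kept 1 ratio between columns within 0.1 log2 in 99.79% to 99.92% of genes, so the tables differ in scaling between columns. FPKM is given as N/A in 16 to 22 rows per column. A count of 0 beside an FPKM of at least 1 occurred in 1 cell, RD29A after ABA 3 h, and was treated as missing.

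Tests planned before the data were examined (edgeR's quasi-likelihood test, camera and fry on gene lists, DESeq2, limma on FPKM, a replicate block, leaving out libraries and other splits of the samples) need a value per replicate and could not be run on combined columns. In their place, chosen after the structure of the tables was seen, log2 ratios of CPM were formed and described by size. CPM used TMM factors from edgeR 4.0.16 in R 4.3.3. Counts below 3 were set to 3 before a ratio was formed, and no ratio was formed where both counts were at or below 3. Ratios with 1 or 2 reads on a side are not printed. Genes with a mean CPM of at least 1 over the 5 columns entered the counts, and a gene was counted as higher or lower from a 2-fold ratio on. The filter planned before the data were examined, filterByExpr, kept 22186 rows. The filter on mean CPM took its place after the structure of the tables was seen, and filterByExpr is given as an alternative. Counting intervals are exact (Clopper-Pearson) at 95%, from SciPy 1.17.1. They and the floors cover counting error only, since no molecular identifiers are named in the labels. A count of 0 stands for up to 0.0170 CPM in the control, 0.0180 after ABA 1 h, 0.0155 after ABA 3 h, 0.0158 after dehydration 1 h and 0.0168 after dehydration 3 h.

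The 28 gene lists, with 452 members, were fixed before the data were examined. Names were compared with the tables and with the RefSeq annotation of TAIR10.1, in which 22432 rows were found by locus code. Of the members, 436 matched a symbol, 14 had no symbol to compare and were kept, and 2 carried another name and were dropped. Of the members kept, 10 were not among the rows. For each list the number of members 2-fold apart, the median and its percentile among 10000 random lists, matched on size and on 20 bins of mean CPM, were computed. TAIR10.1 also served to find neighbouring genes, by gap only, and differences between neighbours were set beside the central 95% of 10000 random relabellings in place of the planned permutation test. Since the build differs from the authors', no coordinates are given. The 1227 rows overlapping another gene on the same strand, and close paralogs, are uncertain where reads could be split.

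Genes are named by a rule fixed before the data were examined, with "called" replaced by the 2-fold limit and the condition on separated replicates dropped. Per comparison it takes the 5 highest and 5 lowest ratios among genes with at least 10 CPM in the higher column, up to 3 members of each list, 2 in the more frequent direction and 1 in the other, and RD29A, RD29B, RAB18, NCED3, HAI1, CYP707A3, P5CS1, PRODH1, ADH1, CCA1, LHY, TOC1, FPA and CPSF30 throughout. Not every eligible gene is printed.

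Alternatives were RLE, upper-quartile and total-count scaling, no filter, filterByExpr, a mean CPM of at least 5, ratios of FPKM with 1 or 0.1 added, neighbour gaps of 500 and 2000 bp, a log2 limit of 2 for induced genes, and low-level neighbours with and without those at 3 reads or fewer in both columns. Low-level genes were also compared within strata of reads in the control and gene length in TAIR10.1, up to 5 bins by 3, with relabelling inside strata. The methods were tested on counts simulated from the control column for dehydration 3 h against control, 22526 rows, with 200 genes given known folds, 50 per fold. Genes drawn at a log2 fold of 1.58 had a median of 1.59, and 100% of them passed 2-fold. Genes drawn at 0.58 had a median of 0.58, and 0% passed. Intervals held the drawn value in 90% to 98% of genes per fold. Of 18322 unchanged genes 0% passed, and 95.1% of intervals held the drawn value. The draws held counting error only, so these values say nothing about differences between replicates or pools. Of 100 random lists, 3% lay outside the central 95%. With reads added evenly per bp to low-level genes, simulated for dehydration 3 h against control, the mean log2 ratio of genes within 500 bp of a same-strand gene minus that of genes beyond 1000 bp was 0.26 unmatched and −0.013 matched (458 and 226 genes), and 1 added to the former came back as 0.99. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 were used.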

Results

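Gene expression was measured by strand-specific RNA sequencing of polyadenylated RNA from 14-day-old Arabidopsis thaliana seedlings of the Columbia accession. Seedlings in liquid medium were harvested untreated, after 1 h or 3 h with 20 µM abscisic acid (ABA, the hormone that plants make when water is short), or after 1 h or 3 h on filter paper out of the medium (dehydration). The series holds 15 libraries, 3 for each of the 5 conditions, and the tables analysed here give 1 combined column per condition. Totals were 180444972 reads for the control, 163762670 for ABA 1 h, 204315702 for ABA 3 h, 178067955 for dehydration 1 h and 179714644 for dehydration 3 h. Because the replicates are combined, no difference below has a replicate check and no test between conditions could be run. Intervals in brackets are exact 95% counting intervals, which cover counting error only, and percentiles of gene lists describe these columns. The control was harvested before treatment, so every comparison with it also spans time and handling. Of 22526 genes, 18876 had a mean CPM (reads scaled to a common library size) of at least 1 and are called measured.

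The comparison of ABA 1 h with the control asks which transcripts differ soon after the hormone is given. The negative regulators of ABA signalling, the clade A PP2C phosphatases, were at least 2-fold higher in 8 of 8 measured members, with a median log2 ratio of 3.68. HAI1 (AT5G59220) stood at 167.3 CPM against 3.20 in the control, a log2 ratio of 5.71 (5.59 to 5.83), and HAI2 (AT1G07430) was 107-fold higher. The ABA receptors lay on the other side, with 6 of 8 members at least 2-fold lower and a median of −1.95, which was −1.16 with no filter or filterByExpr and lay between −1.24 and −1.15 on the FPKM scales. PYL6 (AT2G40330) was 77.7-fold lower, at a log2 ratio of −6.28 (−6.73 to −5.86), and PYL5 (AT5G05440) was 34.7-fold lower. All 17 measured LEA proteins and dehydrins, proteins that accumulate in drying tissue, were at least 2-fold higher, with a median of 3.92 (2.44 on the log2(FPKM + 1) scale with no filter). Among them RD29A (AT5G52310) was 89.7-fold higher, LEA4-5 (AT5G06760) 102-fold, RD29B (AT5G52300) 44.4-fold and RAB18 (AT5G66400) 4.89-fold.

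Transcription factors of the ABA and drought response were at least 2-fold higher in 10 of 12 members after ABA 1 h, among them ANAC019 (AT1G52890) at 37.7-fold, while ANAC055 (AT3G15500) was 2.11-fold lower. DREB and CBF factors were higher in 7 of 8, with CBF3 (AT4G25480) at a log2 ratio of 7.97 (6.92 to 9.29). The ABA-degrading hydroxylase CYP707A1 (AT4G19230) was 13.6-fold higher, and 3 of 5 ABA catabolism genes were at least 2-fold higher. NCED3 (AT3G14440), which catalyses the committed step of ABA synthesis, was 4.59-fold higher, and 1 of 5 measured synthesis genes was at least 2-fold higher, or 3 with no filter. In proline metabolism, the synthesis gene P5CS1 (AT2G39800) was 11.1-fold higher and the degradation gene PRODH1 (AT3G30775) 3.83-fold lower, in a list of proline and raffinose metabolism with 4 of 9 members higher and 1 lower. Heat shock proteins were at least 2-fold lower in 14 of 16 members, with a median of −1.43. Hypoxia genes went both ways: LBD41 (AT3G02550) had a log2 ratio of −4.58 (−4.76 to −4.41) and HRA1 (AT3G10040) was 14.5-fold lower, while PDC1 (AT4G33070) was 5.09-fold higher. The expansin EXPA8 (AT2G40610) was 12.1-fold lower, and photosynthesis genes had a median of −0.54 with 1 of 38 at least 2-fold lower. By size alone the highest ratios included the heat shock factor HSFA6B (listed as AT-HSFA6B, AT3G22830) at 465-fold and EDL3 (AT3G63060) at 119-fold, and the lowest included OXS3 (AT5G56550) at 41.0-fold lower and BT5 (AT4G37610) at 26.5-fold lower. In all, 856 genes were at least 2-fold higher and 969 at least 2-fold lower, so 46.9% of them were higher, against 50.9% with total-count scaling. With no filter on low counts the number higher was 1315, and it was 567 on the log2(FPKM + 1) scale.

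After ABA 3 h the LEA proteins and dehydrins, PP2C phosphatases and ABA receptors had medians farther from the control than after ABA 1 h, a difference that was not tested. The median of the LEA proteins and dehydrins was 6.98 over 16 members with a ratio, all 16 at least 2-fold higher, with RD29B at a log2 ratio of 10.95 (10.59 to 11.32), LEA7 (AT1G52690) at 10.63 (10.22 to 11.08) and RAB18 at 6.34 (6.23 to 6.45). RD29A is listed with a count of 0 in this column and an FPKM of 3959.86, against an FPKM of 7.11 in the control, so its count was treated as missing and its log2 ratio of FPKM was 9.12. The PP2C phosphatases had a median of 4.54, with HAI1 104-fold and HAI2 368-fold higher, and HAI3 (AT2G29380) rested on 3 control reads at a log2 ratio of 11.25 (9.71 to 13.53). The receptors had a median of −2.31 (−1.41 on the log2(FPKM + 1) scale with no filter), with PYL6 112-fold and PYL4 (AT2G38310) 39.7-fold lower. CYP707A1 was 52.2-fold higher, while CYP707A3 (AT5G45340), another hydroxylase, had a log2 ratio of 0.09 (0.02 to 0.16). P5CS1 reached 1370 CPM, 49.1-fold above the control.

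DREB and CBF factors were at least 2-fold higher after ABA 3 h in 6 of 7 members with a ratio and lower in 1, a number that was 0 on the FPKM scales and at a mean CPM of at least 5. Their median was 3.12, or 1.98 on the log2(FPKM + 1) scale and 1.43 on it with no filter. ABA and drought transcription factors were higher in 9 of 12, with a median of 2.99, and ABA catabolism genes in 3 of 5, with a median of 3.07. Photosynthesis genes had a median of −0.89 with 11 of 38 at least 2-fold lower, a number that was 18 with upper-quartile scaling, led by RBCS1B (AT5G38430) at 4.44-fold lower. RBCS1B has close relatives whose reads the counting could have split. Auxin response genes were at least 2-fold lower in 11 of 21, with a median of −1.06 that was −0.38 among genes of mean CPM of at least 5. Heat shock proteins had a median of −0.94 with 7 of 16 lower. Hypoxia genes had a median of −1.50 (−0.98 on the log2(FPKM + 1) scale and −0.96 at a mean CPM of at least 5) and 8 of 14 lower, yet ADH1 (AT1G77120), alcohol dehydrogenase, was 11.1-fold higher and the sucrose synthase SUS1 (AT5G20830) 11.5-fold higher. Expansins and xyloglucan endotransglucosylases were lower in 6 of 21, with EXPA8 at a log2 ratio of −4.33 (−4.44 to −4.22). The receptor-like kinase CRK30 (AT4G11460) was 155-fold lower and the LEA-family gene AT3G17520 was at 180 CPM against 5 reads in the control. In all, 1721 genes were at least 2-fold higher and 1471 lower. The higher genes were 53.9% of these with TMM scaling, 46.4% with upper-quartile and 49.9% with total-count scaling, so which side holds more genes depends on the scaling. With no filter the number lower was 2227, and at a mean CPM of at least 5 it was 915.

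Seedlings dehydrated for 1 h, with no added hormone, were set against the control. DREB and CBF factors were at least 2-fold higher in 8 of 8, with a median of 6.02 that lay between 2.99 and 3.91 on the FPKM scales. CBF3 was at a log2 ratio of 8.98 (7.94 to 10.30) and CBF1 (AT4G25490) at 7.66 (6.78 to 8.72). NCED3 was 19.3-fold higher. LEA proteins and dehydrins were higher in 15 of 17, with COR15B (AT2G42530) at 124-fold and RD29A at 68.1-fold, while RAB18 had a log2 ratio of −0.49 (−0.66 to −0.32). PP2C phosphatases were higher in 7 of 8 with a median of 1.66, or in 4 with a median of 1.08 on the log2(FPKM + 1) scale, among them HAI1 at 9.12-fold. Jasmonate synthesis and response genes were at least 2-fold higher in 16 of 24 with a median of 1.48, among them LOX3 (AT1G17420), a lipoxygenase of jasmonate synthesis, at 15.2-fold and CYP94B3 (AT3G48520), which inactivates the hormone, at a log2 ratio of 4.19 (4.04 to 4.34). Cytokinin response genes were higher in 6 of 10, with ARR15 (AT1G74890) 8.11-fold and ARR7 (AT1G19050) 6.66-fold higher. Touch and wound genes were higher in 8 of 20 and lower in 2, with RRTF1 (AT4G34410) 37.3-fold higher and TCH4 (AT5G57560) 3.89-fold lower.

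Lower after dehydration 1 h were the heat shock proteins, in 12 of 16 with a median of −1.41 and MBF1C (AT3G24500) at 10.5-fold lower. The ABA receptors were lower in 6 of 8, with PYL5 10.1-fold lower. Photosynthesis genes had a median of −0.74 with 5 of 38 at least 2-fold lower (3 with total-count scaling), and aquaporins, the water channels, had a median of −0.69 with 3 of 19 lower. The SAUR-family gene AT4G34770 was 49.6-fold lower, PKS4 (AT5G04190) 32.8-fold and BEE3 (AT1G73830) 30.0-fold. CIB1 (AT4G34530) had 58 reads against 10743, but it overlaps another gene on its strand and its FPKM is given as N/A, so this ratio is uncertain. In all, 1458 genes were at least 2-fold higher and 1060 lower, so 57.9% of them were higher, against 67.2% with total-count and 54.1% with upper-quartile scaling. The number higher was 2295 with no filter and 940 on the log2(FPKM + 1) scale.

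After dehydration 3 h, NCED3 stood at 189.4 CPM, 73.4-fold above the control. COR15B was at a log2 ratio of 10.70 (10.29 to 11.15), COR15A (AT2G42540) at 9.33 (9.15 to 9.50), RD29A at 8.15 (8.10 to 8.20) and RD29B at 6.70 (6.34 to 7.07), and 17 of 17 LEA proteins and dehydrins were at least 2-fold higher. The ABA receptors split: PYL4 was 14.7-fold lower and PYL6 10.2-fold lower, while PYL7 (AT4G01026) was 10.3-fold higher. Of 8 members 2 were at least 2-fold higher, or 4 with no filter, and 6 lower. The galactinol synthases GOLS3 (AT1G09350) and GOLS2 (AT1G56600), which start raffinose synthesis, were 371-fold and 136-fold higher, and P5CS1 was 17.1-fold higher, with 5 of 9 proline and raffinose genes higher. Jasmonate genes were higher in 20 of 24, with JAZ10 (AT5G13220) at 15.2-fold. Touch and wound genes were higher in 12 of 20, with a median of 1.56 (1.03 at a mean CPM of at least 5). Aquaporins were higher in 8 of 19 and lower in 3, with PIP2;3 (AT2G37180) at 1130 CPM, 11.5-fold above the control, and PIP1;5 (AT4G23400) 3.42-fold lower. PIP2;3 has close relatives whose reads the counting could have split.

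Ethylene genes were lower in 9 of 17 after dehydration 3 h, with the receptor ETR2 (AT3G23150) 5.76-fold lower, although the synthesis gene ACS2 (AT1G01480) was 26.9-fold higher. Auxin response genes were lower in 10 of 21 and higher in 3, with a median of −0.65 that turned to 0.15 among genes of mean CPM of at least 5. Heat shock proteins were lower in 13 of 16 and photosynthesis genes in 13 of 38. EXPA8 was 70.6-fold lower and EXPA10 (AT1G26770) 7.49-fold higher among 10 lower and 4 higher of 21 cell wall genes. The AP2-domain gene AT4G28140 stood at 500.8 CPM against 0.294, a log2 ratio of 10.74 (10.34 to 11.16). In all, 1989 genes were at least 2-fold higher and 1225 lower, and the number higher was 3069 with no filter.

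The series concerns the 3′ ends of transcripts, so factors of mRNA 3′-end processing were a list of their own. After ABA none of the 25 measured members was 2-fold apart from the control at 1 h or at 3 h. After dehydration 2 relatives of the yeast factor Pcf11 stood out: PCFS5 (AT5G43620) was 17.2-fold higher at 1 h and 19.9-fold higher at 3 h, and PCFS1 (AT1G66500) was 10.8-fold and 13.4-fold higher. They were 2 of 4 members at least 2-fold higher at 1 h and the 2 members higher at 3 h. FPA (AT2G43410), an RNA-binding protein that promotes proximal polyadenylation, was 2.40-fold higher after dehydration 1 h and 1.85-fold higher after 3 h, against 1.88-fold after ABA 1 h and 1.16-fold after ABA 3 h. CPSF30 (AT1G30460), a polyadenylation factor subunit, had log2 ratios between −0.35 and 0.01 in the 4 comparisons with the control. The list median was 0.38 after dehydration 1 h, at percentile 99.9 of 10000 random lists of matched expression and above their central 95% of −0.20 to 0.25. It was 0.04 after dehydration 3 h, at percentile 69.1, and 0.16 and 0.13 after ABA 1 h and ABA 3 h, all 3 inside the central 95%. Small RNA machinery and exoribonucleases had 0 of 17 members 2-fold apart from the control in any of the 4 comparisons.

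**Figure D1:**
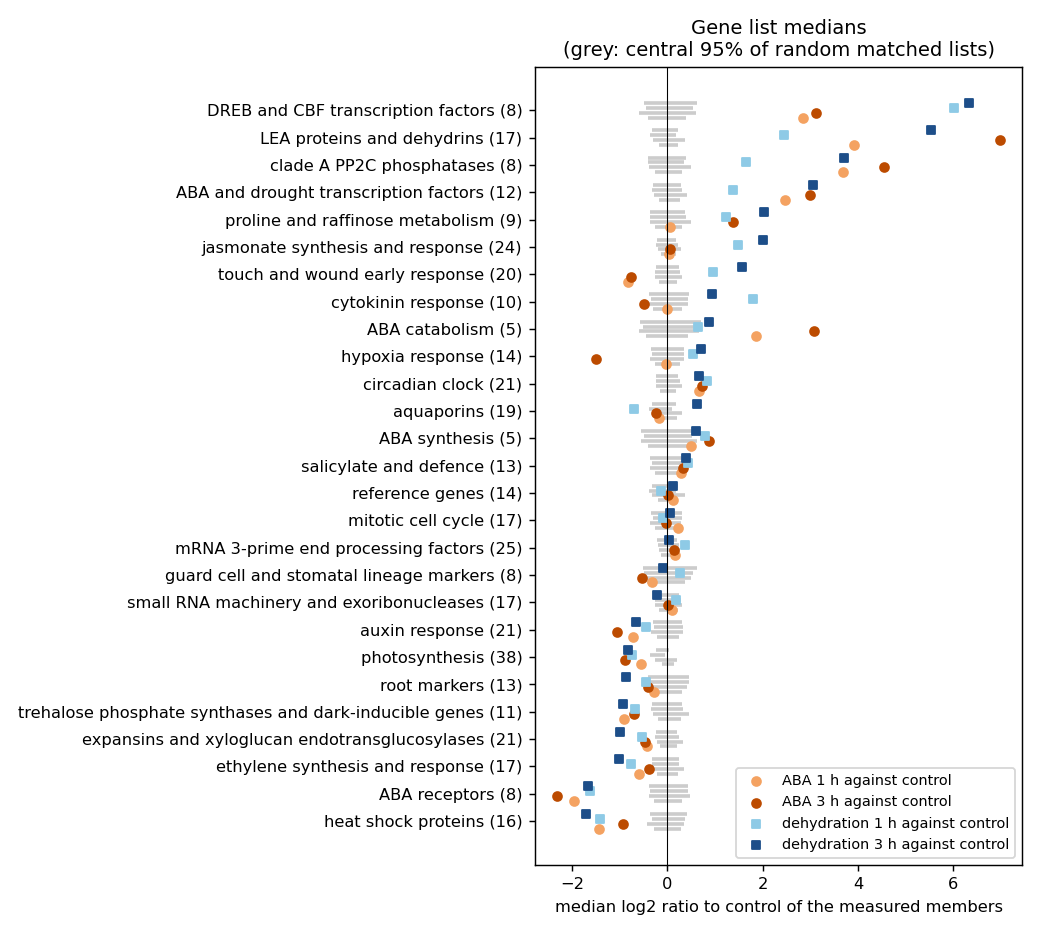
Median log2 ratio to the control (horizontal axis) of the measured members of each gene list (vertical axis, number of members in brackets), circles for ABA and squares for dehydration, darker at 3 h. Grey lines span the central 95% of 10000 random lists of matched expression; LEA proteins and dehydrins lie at 6.98 after ABA 3 h and 5.53 after dehydration 3 h, and jasmonate genes at 0.07 and 2.01.

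Clock genes differed from the control after both treatments. FKF1 (AT1G68050) was 21.5-fold higher after ABA 3 h and 31.5-fold higher after dehydration 3 h, and TOC1 (AT5G61380) was 2.68-fold and 3.29-fold higher. LHY (AT1G01060) was 5.11-fold lower after ABA 3 h and had a log2 ratio of −1.72 (−1.79 to −1.65) after dehydration 3 h. CCA1 (AT2G46830) was 3.03-fold lower after ABA 3 h and had a log2 ratio of −0.14 (−0.18 to −0.10) after dehydration 3 h. The list had 7 higher and 7 lower of 21 after ABA 3 h, and 10 higher and 5 lower after dehydration 3 h. Salicylate and defence genes were higher in 3 of 13 after ABA 3 h, or 5 with no filter, and in 2 of 13 after dehydration 3 h, with EDS5 (AT4G39030) 3.51-fold higher in the latter. Among 11 trehalose phosphate synthases and dark-inducible genes, 5 were lower and 2 higher after ABA 3 h, and 4 lower and 1 higher after dehydration 3 h. DIN10 (AT5G20250) was 7.43-fold and 4.17-fold lower.

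Markers of other cell types were set beside these groups. Root markers had medians of −0.28 and −0.40 after ABA at 1 h and at 3 h, and of −0.44 and −0.86 after dehydration at 1 h and at 3 h. The 2 dehydration medians lay below the central 95% of random lists. Few members were 2-fold apart, though. Of 13 measured, 4 were lower and 1 higher after dehydration 1 h, and 1 lower and 1 higher after dehydration 3 h, where the mean was −0.21. WOX5 (AT3G11260), a marker of the root quiescent centre, went the other way and was 44.0-fold higher after dehydration 3 h. Guard cell and stomatal lineage markers had medians of −0.33, −0.54, 0.28 and −0.08, each inside the central 95% of random lists, with MYB60 (AT1G08810) 4.32-fold lower after ABA 3 h. None of the 6 seed storage and oil body markers in the table reached the level to be measured, and with no filter 4 were at least 2-fold higher after ABA 1 h and 6 after dehydration 3 h. Genes under a mean CPM of 1 were higher after dehydration 3 h more widely, with mean log2 ratios of 1.48 and 0.36 in the sets described at the end. The number after dehydration 3 h therefore does not single out seed genes. Mitotic cell cycle genes and reference genes had 0 of 17 and 0 of 14 members 2-fold apart from the control in each of the 4 comparisons.

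Between the times of ABA treatment, RD29B was a further 44.5-fold higher at 3 h than at 1 h and RAB18 16.6-fold. SAG29 (AT5G13170) was 68.9-fold higher and LTP4 (AT5G59310), a lipid transfer protein, 93.0-fold higher. All 16 LEA proteins and dehydrins with a ratio were at least 2-fold higher at 3 h. The clock genes CCA1 and PRR9 (AT2G46790) were 5.05-fold and 4.39-fold lower at 3 h, and the haemoglobin gene HB1 (AT2G16060) 4.49-fold lower. In all, 928 genes were at least 2-fold higher at 3 h and 452 lower. The number lower was 966 with no filter, 222 at a mean CPM of at least 5 and 225 on the log2(FPKM + 1) scale. The share of higher genes among those 2-fold apart was 67.2% and became 57.1% with total-count scaling, which lowers the median of all genes by 0.10.

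Between the times of dehydration, LEA7 was 53.4-fold higher at 3 h than at 1 h, RD29B 23.3-fold and RAB18 12.9-fold, and 17 of 17 LEA proteins and dehydrins were at least 2-fold higher. Aquaporins were higher at 3 h in 11 of 19 and lower in 0, with PIP2;3 at 13.2-fold and PIP2;5 (AT3G54820) at 8.11-fold. PYL7 was 10.2-fold higher and PYL9 (AT1G01360) 4.01-fold higher. The lowest ratios belonged to the xylosidase BXL1 (AT5G49360) at 4.78-fold lower and the extensin-like genes AT1G23720 and AT3G28550 at 4.75-fold and 4.34-fold lower. In all, 1007 genes were at least 2-fold higher at 3 h and 280 lower. The number higher was 1579 with no filter, and the number lower ran from 135 on the log2(FPKM + 1) scale to 515 with no filter. The share of higher genes was 78.2%, and it was 67.0% with total-count scaling, which lowers the median of all genes by 0.10.

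Set directly against ABA at the same time, dehydration 1 h had higher jasmonate genes in 18 of 24 members, with JAZ8 (AT1G30135) 20.2-fold and LOX4 (AT1G72520) 9.87-fold higher. Touch and wound genes were higher in 17 of 20, with RRTF1 43.5-fold higher, and DREB and CBF factors in 7 of 8, or 3 on the log2(FPKM + 1) scale. Dehydrated seedlings were also moved out of the medium onto filter paper, so comparisons with ABA at either time span handling as well. NCED3 was 4.19-fold higher and PRODH1 4.28-fold higher. PP2C phosphatases were lower than after ABA in 7 of 8, with HAI1 5.73-fold lower. Of 17 LEA proteins and dehydrins 7 were lower, 1 was higher and 9 were not 2-fold apart, with a median of −0.48, and among the lower LEA7 was 26.3-fold, RD29B 9.97-fold and RAB18 6.88-fold lower. RD29A differed little, with a log2 ratio of −0.40 (−0.40 to −0.39). PCFS5 was 9.29-fold and PCFS1 6.32-fold higher than after ABA. In all, 1019 genes were at least 2-fold higher after dehydration and 661 lower. The number higher was 1816 with no filter, and the number lower was 438 at a mean CPM of at least 5.

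At 3 h, dehydration exceeded ABA at NCED3 by 8.31-fold, at PYL7 by 12.0-fold and at GOLS3 by 77.2-fold. Jasmonate genes were higher in 19 of 24, touch and wound genes in 17 of 20 and aquaporins in 9 of 19. Lower than after ABA were HAI1 by 3.23-fold, CYP707A2 (AT2G29090) by 16.2-fold and CYP707A1 by 7.03-fold, the seed protein gene EM6 (AT2G40170) by 30.6-fold and P5CS1 by 2.88-fold. PP2C phosphatases were lower in 5 of 8, ABA catabolism genes in 3 of 5, and LEA proteins and dehydrins in 7 of 16 with 1 higher. The highest ratio by size was AT5G25600, with 2501 reads after dehydration 3 h and 0 after ABA 3 h. With the 0 set to 3 reads it was 906-fold higher. It begins 66 bp behind the end of RD22 (AT5G25610) on the same strand, which had 160372 reads after dehydration 3 h and 250615 after ABA 3 h. Reads past the end of RD22 and reads of AT5G25600 cannot be told apart in these counts. The phloem protein gene PP2-A5 (listed as ATPP2-A5, AT1G65390) was 155-fold higher. In all, 1728 genes were at least 2-fold higher after dehydration and 1287 lower, and the number higher was 2996 with no filter and 1102 at a mean CPM of at least 5.

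**Figure D2:**
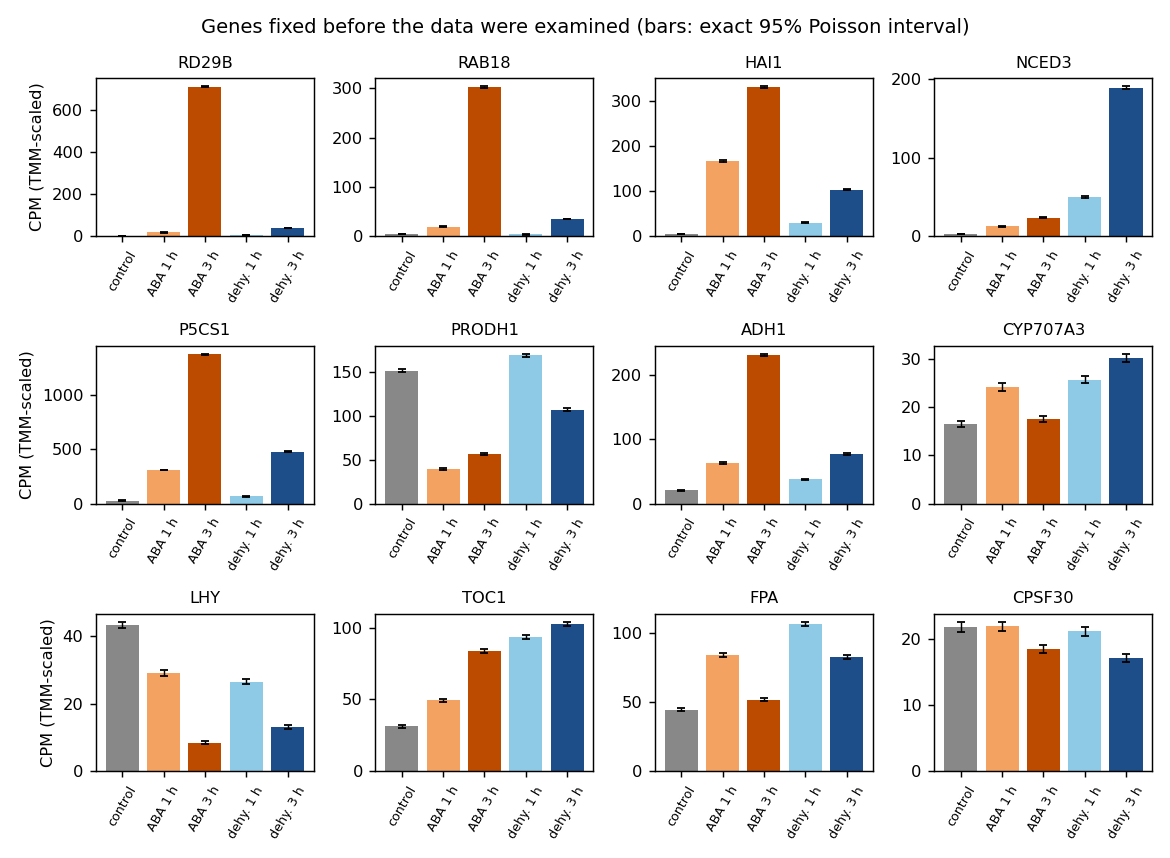
Level of 12 genes named in advance, in CPM after TMM scaling (vertical axes, linear, from 0), in the columns for the control (grey), ABA (orange) and dehydration (blue), darker at 3 h than at 1 h. Each bar is 1 combined column and error lines are exact 95% Poisson intervals for counting error; NCED3 reaches 189.4 CPM after dehydration 3 h against 22.8 after ABA 3 h, and HAI1 102.5 against 331.3.

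Whether the difference between the treatments changed between the times could not be tested, and genes were counted by size. The log2 ratio of dehydration 3 h to 1 h minus that of ABA 3 h to 1 h was at least 1 in 1077 genes and at most −1 in 867, so 55.4% were on the first side, against 63.0% with upper-quartile scaling. Aquaporins were on the first side in 11 of 19 with a median of 1.45, and ABA and drought transcription factors in 8 of 12 with a median of 1.04. ABA catabolism genes were on the other side in 3 of 5, with a median of −1.73. The first number was 1859 with no filter and 676 at a mean CPM of at least 5.

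The responses to ABA and dehydration were compared across genes, which are not independent replicates. Pearson's r of the log2 ratios to the control was 0.659 at 1 h and 0.608 at 3 h, and Spearman's rho was 0.633 and 0.515. Both comparisons share the control column, and unchanged columns simulated against it gave r of 0.504 and 0.511. The covariance was 0.399 at 1 h and 0.644 at 3 h, against simulated values of 0.00248 and 0.00249. The simulation holds counting error only, so part of the excess may come from other chance differences of the shared control column, which could not be split. At 3 h, 931 genes were at least 2-fold higher after both treatments, where independent lists of the same sizes share 181, and 565 were lower after both, where independent lists share 95.5. These lists are not independent, since they share the control column, and the overlap that this alone gives was not simulated. Another 29 genes were 2-fold higher after ABA 3 h and lower after dehydration 3 h, and 87 the other way, against 7 and 31 at 1 h. The ratios of 3 h to 1 h, which have no column in common, had r of 0.353 and a weaker rho of 0.217 between the treatments. Both span the step from 1 h to 3 h, so time and handling common to the treatments may add to this r. The values against the control also span time and handling, which cannot be told apart from a shared response.

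Reads that run past the end of a gene would be counted to the next gene on its strand, so neighbours of genes at least 2-fold higher were compared. Measured neighbours within 1000 bp on the 3′ side had a mean log2 ratio of 0.47 after dehydration 3 h, over 394 neighbours, and those on the 5′ side 0.47, over 344. The difference was 0.01 and lay inside the range of −0.19 to 0.19 that holds 95% of 10000 random relabellings. It was −0.03 after dehydration 1 h, −0.16 after ABA 3 h and −0.12 after ABA 1 h, each inside its range. Neighbours with a mean CPM under 1, an alternative chosen after seeing the data, had means of 2.44 on the 3′ side (73 neighbours) and 1.26 on the 5′ side (54) after dehydration 3 h. Their difference of 1.19 lay outside the range of −0.68 to 0.66, while those of 0.55 after dehydration 1 h, 0.33 after ABA 3 h and −0.14 after ABA 1 h lay inside their ranges. A ratio needs more than 3 reads in at least 1 of the 2 columns, and with no neighbour left out for low reads the difference was 1.296 over 73 and 59 neighbours, outside the range of −0.66 to 0.66.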

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

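The tests in this part were all chosen after the results were seen. Differences between the treatments or times below were not tested, since each condition is 1 combined column.

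RD29A drew attention because the FPKM column, which the counts do not use, lists 3959.86 after ABA 3 h where the count is 0. Absence of the transcript is argued against by the log2 ratio of its FPKM to the control, 9.12. Its FPKM stands for 1972984 reads, from the reads per FPKM in the other columns, and the count of the neighbouring RD29B holds 7.005% of that number, so a transfer of its reads to RD29B is argued against too. What set the count to 0 stays open, and no biological explanation was tested.

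Clock genes differed from a control harvested before treatment. Of 21 members, 20 lay on the same side of the control after ABA 3 h and after dehydration 3 h, at percentile 99.8 of random lists whose median was 15. That is consistent with time of day, but a response that ABA and dehydration share would give the same result, and the design has no untreated seedlings harvested at 3 h. Responses particular to a treatment would separate the treatments at the same hour, and 4 members (CCA1, PRR5, PRR9 and RVE6) were at least 2-fold apart between dehydration 3 h and ABA 3 h, against 14 between ABA 3 h and the control. Time of day does not give the gap between treatments in these 4 if both began at the same hour, which the labels do not state, and with 1 column per condition the gap has no replicate check; for the differences from the control, time of day and treatment cannot be told apart.

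Touch and wound genes lay on opposite sides of the control, with medians of −0.82 after ABA 1 h and 0.96 after dehydration 1 h, and of −0.76 after ABA 3 h and 1.56 after dehydration 3 h, or 1.03 at a mean CPM of at least 5. Hypoxia genes had medians of −1.50 after ABA 3 h and 0.70 after dehydration 3 h, where their mean was −0.03. The latter median was 1.395 at a mean CPM of at least 5 and 0.25 on the log2(FPKM + 1) scale with no filter, and the former −0.96 at a mean CPM of at least 5. Aquaporins had medians of −0.69 after dehydration 1 h and 0.62 after dehydration 3 h.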

How the results depend on the processing

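Total-count scaling, the FPKM ratios, the count of RD29A as deposited neighbours with a mean CPM under 1 and the other sets of low-level genes were tests chosen after seeing the data. The planned filter was filterByExpr, and setting it against a mean CPM of at least 1 as an alternative was chosen after seeing the data too. Under RLE, upper-quartile and total-count scaling, 263 results that answer a comparison stayed close to the values reported. Counts stayed within 1.5 times, list medians moved by less than the distance from the middle to the edge of the central 95% of random lists, and r stayed inside the interval of 1000 bootstrap draws over genes. A change of scaling moves all log2 ratios of a comparison by 1 constant, here 0.12 or less. It can change r only through the filter, and list medians hardly beyond that constant, so their staying close is no support. The side with more genes did change for ABA 1 h and ABA 3 h against control, as given above. Ratios of single genes, held to their narrow counting intervals, and numbers of list members, held to 1.5 times, moved more often: 9 moved and 1052 stayed with RLE, 157 and 904 with upper-quartile, 219 and 842 with total-count scaling. With no filter, as with filterByExpr, 37 moved and 1024 stayed. The numbers were 77 and 886 at a mean CPM of at least 5, 121 and 905 with FPKM + 0.1, 485 and 541 with FPKM + 1, and 518 and 538 with FPKM + 1 unfiltered. Total-count scaling raised the median of all genes by 0.12 for dehydration 1 h against control. The 4 differences between neighbours moved by less than the same distance in their random range under gaps of 500 and 2000 bp and a log2 limit of 2. No paired analysis was possible because the deposited columns combine the replicates of a condition, and for the same reason the edgeR, DESeq2, limma, camera and fry tests, fits on the compared groups alone, the replicate block, leaving out libraries and other splits of the samples were not run. Depth limits little for genes near 1 CPM or above in both columns, since 1 CPM stands for 167 to 194 reads. The filter is on the mean over the columns, so a measured gene can still have few control reads, as HAI3 does, and its interval is then wide. Counting error is the only error known. In the values that follow, CPM 5 means a mean CPM of at least 5. Filters change counts by the number of genes they admit, and adding 1 to FPKM shrinks ratios of low genes by construction. The cause was not tested for the others.

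ABA 1 h against control had 1315 (no filter), 1304 (filterByExpr) and 567 (FPKM + 1) genes higher, against 856. ABA 3 h against control had 2227 (no filter) and 915 (CPM 5) genes lower, against 1471. Dehydration 1 h against control had 2295 (no filter), 2276 (filterByExpr) and 940 (FPKM + 1) genes higher, against 1458. Dehydration 3 h against control had 3069 (no filter) and 3023 (filterByExpr) genes higher, against 1989. ABA 3 h against ABA 1 h had 966 (no filter), 222 (CPM 5), 959 (filterByExpr), 225 (FPKM + 1) and 229 (FPKM + 1 unfiltered) genes lower, against 452. Dehydration 3 h against dehydration 1 h had 1579 (no filter) and 1534 (filterByExpr) genes higher, against 1007. Dehydration 3 h against dehydration 1 h had 515 (no filter), 181 (CPM 5), 503 (filterByExpr), 135 (FPKM + 1) and 139 (FPKM + 1 unfiltered) genes lower, against 280. Dehydration 1 h against ABA 1 h had 1816 (no filter) and 1795 (filterByExpr) genes higher, against 1019. Dehydration 1 h against ABA 1 h had 438 (CPM 5) genes lower, against 661. Dehydration 3 h against ABA 3 h had 2996 (no filter), 1102 (CPM 5) and 2937 (filterByExpr) genes higher, against 1728. Interaction of treatment and time had 1859 (no filter), 676 (CPM 5) and 1842 (filterByExpr) genes higher, against 1077.

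ABA receptors had medians of −1.16 (no filter, filterByExpr), −1.21 (FPKM + 1), −1.24 (FPKM + 0.1) and −1.15 (FPKM + 1 unfiltered) against −1.95 for ABA 1 h against control and −1.69 (FPKM + 1) and −1.41 (FPKM + 1 unfiltered) against −2.31 for ABA 3 h against control. For ABA receptors, medians were −1.16 (FPKM + 1 unfiltered) against −1.65 for dehydration 3 h against control and 0.37 (no filter, filterByExpr, FPKM + 1, FPKM + 1 unfiltered) against 0.65 for dehydration 1 h against ABA 1 h. Clade A PP2C phosphatases had medians of 2.93 (FPKM + 1 unfiltered) against 3.68 for ABA 1 h against control and 5.03 (no filter, filterByExpr), 3.94 (FPKM + 1, FPKM + 1 unfiltered) and 4.01 (FPKM + 0.1) against 4.54 for ABA 3 h against control. For clade A PP2C phosphatases, medians were 1.14 (no filter, filterByExpr), 1.08 (FPKM + 1), 1.11 (FPKM + 0.1) and 0.996 (FPKM + 1 unfiltered) against 1.66 for dehydration 1 h against control and 3.09 (FPKM + 1) and 2.83 (FPKM + 1 unfiltered) against 3.71 for dehydration 3 h against control. For clade A PP2C phosphatases, medians were −2.51 (no filter, filterByExpr), −1.94 (FPKM + 1, FPKM + 1 unfiltered) and −1.95 (FPKM + 0.1) against −2.24 for dehydration 1 h against ABA 1 h. LEA proteins and dehydrins had medians of 3.25 (FPKM + 1) and 2.44 (FPKM + 1 unfiltered) against 3.92 for ABA 1 h against control and 6.49 (no filter, CPM 5, filterByExpr), 6.34 (FPKM + 1), 6.56 (FPKM + 0.1) and 6.11 (FPKM + 1 unfiltered) against 6.98 for ABA 3 h against control. For LEA proteins and dehydrins, medians were 1.99 (FPKM + 1 unfiltered) against 2.45 for dehydration 1 h against control and 5.24 (FPKM + 1) and 4.499 (FPKM + 1 unfiltered) against 5.53 for dehydration 3 h against control. For LEA proteins and dehydrins, medians were 2.87 (no filter, CPM 5, filterByExpr), 2.72 (FPKM + 1, FPKM + 0.1) and 2.68 (FPKM + 1 unfiltered) against 3.27 for ABA 3 h against ABA 1 h and 1.91 (FPKM + 1 unfiltered) against 3.003 for dehydration 3 h against dehydration 1 h. For LEA proteins and dehydrins, medians were −1.11 (no filter, filterByExpr) against −0.81 for dehydration 3 h against ABA 3 h. ABA and drought transcription factors had medians of 1.999 (FPKM + 1, FPKM + 1 unfiltered) against 2.48 for ABA 1 h against control. DREB and CBF transcription factors had medians of 2.08 (FPKM + 1), 3.82 (FPKM + 0.1) and 1.97 (FPKM + 1 unfiltered) against 2.84 for ABA 1 h against control and 1.98 (FPKM + 1) and 1.43 (FPKM + 1 unfiltered) against 3.12 for ABA 3 h against control. For DREB and CBF transcription factors, medians were 4.303 (CPM 5), 3.398 (FPKM + 1), 3.91 (FPKM + 0.1) and 2.99 (FPKM + 1 unfiltered) against 6.02 for dehydration 1 h against control and 5.63 (CPM 5), 3.85 (FPKM + 1), 5.603 (FPKM + 0.1) and 3.33 (FPKM + 1 unfiltered) against 6.32 for dehydration 3 h against control. For DREB and CBF transcription factors, medians were −0.13 (FPKM + 1), −0.1003 (FPKM + 0.1) and −0.078 (FPKM + 1 unfiltered) against −0.902 for ABA 3 h against ABA 1 h and 0.91 (FPKM + 0.1) against 0.48 for dehydration 3 h against dehydration 1 h. Auxin response had medians of −0.26 (CPM 5) against −0.72 for ABA 1 h against control and −0.38 (CPM 5) against −1.06 for ABA 3 h against control. For auxin response, medians were 0.15 (CPM 5) against −0.65 for dehydration 3 h against control and −0.039 (CPM 5) against −0.31 for dehydration 3 h against dehydration 1 h. For auxin response, medians were 0.11 (CPM 5) against −0.35 for interaction of treatment and time. Hypoxia response had medians of −0.31 (no filter, filterByExpr) and 0.44 (CPM 5) against −0.017 for ABA 1 h against control and −0.96 (CPM 5), −0.98 (FPKM + 1, FPKM + 1 unfiltered) and −1.12 (FPKM + 0.1) against −1.497 for ABA 3 h against control. For hypoxia response, medians were 1.395 (CPM 5) and 0.25 (FPKM + 1 unfiltered) against 0.703 for dehydration 3 h against control and 0.35 (FPKM + 1 unfiltered) against 0.78 for dehydration 3 h against ABA 3 h. For hypoxia response, medians were −0.33 (CPM 5) against 0.091 for interaction of treatment and time. ABA synthesis had medians of 1.48 (no filter, filterByExpr) against 0.88 for ABA 3 h against control and 1.33 (no filter, filterByExpr) against 0.61 for dehydration 3 h against control. Proline and raffinose metabolism had medians of 0.65 (FPKM + 1, FPKM + 1 unfiltered) against 1.37 for ABA 3 h against control and 1.54 (FPKM + 1, FPKM + 1 unfiltered) against 2.03 for dehydration 3 h against control. Jasmonate synthesis and response had medians of 1.22 (FPKM + 1 unfiltered) against 1.48 for dehydration 1 h against control and 1.497 (no filter, filterByExpr), 1.43 (CPM 5) and 1.47 (FPKM + 1 unfiltered) against 1.72 for dehydration 1 h against ABA 1 h. Cytokinin response had medians of 1.29 (FPKM + 1) and 0.699 (FPKM + 1 unfiltered) against 1.79 for dehydration 1 h against control and 1.604 (no filter, CPM 5, filterByExpr) and 0.31 (FPKM + 1 unfiltered) against 0.94 for dehydration 3 h against control. For cytokinin response, medians were 2.099 (no filter, CPM 5, filterByExpr) and 0.57 (FPKM + 1 unfiltered) against 1.26 for dehydration 1 h against ABA 1 h and 1.82 (no filter, filterByExpr), 1.79 (CPM 5) and 0.603 (FPKM + 1 unfiltered) against 1.33 for dehydration 3 h against ABA 3 h. Touch and wound early response had medians of 1.03 (CPM 5) against 1.56 for dehydration 3 h against control and 0.26 (FPKM + 1, FPKM + 1 unfiltered) against 0.43 for ABA 3 h against ABA 1 h. For touch and wound early response, medians were 1.48 (CPM 5), 1.496 (FPKM + 1) and 1.50002 (FPKM + 0.1) against 1.69 for dehydration 1 h against ABA 1 h. ABA catabolism had medians of −0.32 (CPM 5) against 0.21 for dehydration 3 h against dehydration 1 h. Root markers had medians of −0.41 (CPM 5) against 0.14 for dehydration 3 h against dehydration 1 h and −0.39 (CPM 5) against 0.11 for dehydration 3 h against ABA 3 h. Ethylene synthesis and response had medians of −0.67 (CPM 5) against −0.34 for dehydration 3 h against ABA 3 h.

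Auxin response genes after dehydration 3 h turned from −0.65 to 0.15 with CPM 5, their interaction of treatment and time from −0.35 to 0.11, and RD29A after ABA 3 h from 9.12 to −10.20 with the count of 0 taken as deposited. Pearson's r at 1 h was 0.631 with no filter and with filterByExpr and 0.683 with CPM 5, against 0.659. At 3 h it was 0.562 with no filter and with filterByExpr, 0.649 with CPM 5 and 0.586 with FPKM + 1 unfiltered, against 0.608. For neighbours with a mean CPM under 1 the differences were 0.33 after ABA 3 h, 0.55 after dehydration 1 h and 1.19 after dehydration 3 h, against −0.16, −0.03 and 0.01, and with none left out for low reads 0.18, 0.447 and 1.296; only those after dehydration 3 h lay outside their ranges. Of the 24 differences between low-level genes computed in the same way, 24 stayed within the random distance with all genes kept, 17 stayed and 7 moved with more than 3 reads in the reference column, and of 12 matched on control reads and length 6 stayed and 6 moved.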

Other observations

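The tests in this part were chosen after the pattern was seen, except that the test by distance, on genes with a ratio, was set down before its result was seen. Families come from the annotation text of the deposited table, with at least 10 measured members and 2000 random lists, and were looked at after the lists above.

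SAUR-like auxin-responsive genes, small early auxin genes linked to cell growth, were at least 2-fold lower in 25 of 43 measured members after ABA 3 h (median −1.47) and in 26 of 43 after dehydration 3 h (median −1.44). Proline-rich extensin-like genes, which encode cell wall proteins, were lower in 10 of 11 after dehydration 3 h, with a median of −2.54. Their median after ABA 1 h was 0.34, where both treatment and time differ. These values therefore do not show whether the lower level is particular to dehydration. Genes of the TIR-NBS-LRR class of disease resistance proteins were higher in 18 of 48 after dehydration 1 h, with a median of 0.82. ABC-2 type transporters were higher in 10 of 18 after ABA 3 h, with a median of 1.21. Genes annotated with an integrase-type DNA-binding domain, the class that holds AP2 factors, were higher in 26 of 52 and lower in 9 after dehydration 3 h.

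Low-level genes, with a mean CPM under 1, showed a pattern that depends on what lies on their 5′ side. Those with a measured gene of the same strand ending within 1000 bp had a mean log2 ratio of 1.48 after dehydration 3 h over 648 genes, against 0.36 over 236 genes whose neighbour points away. The difference was 0.78 after dehydration 1 h, 0.09 after ABA 1 h and −0.19 after ABA 3 h, the last 2 inside the random-relabelling range. A ratio needs more than 3 reads in at least 1 of the 2 columns, so the sets differ between comparisons and a gene can enter through the column in which it is higher. With all 666 and 248 genes kept, counts under 3 set to 3, the difference was 1.101 after dehydration 3 h (range −0.26 to 0.26), 0.72 after dehydration 1 h, 0.06 after ABA 1 h and −0.199 after ABA 3 h, the last 2 inside their ranges. Among genes with more than 3 control reads, 464 of them behind a gene of the same strand, it was smaller, 0.86 after dehydration 3 h (−0.27 to 0.26) and 0.605 after dehydration 1 h (−0.21 to 0.199), and 0.17 after ABA 1 h lay outside its range of −0.14 to 0.14. Genes behind a same-strand gene had fewer control reads, a median of 14 against 22, and reads added to few raise a ratio more. Matched on control reads and gene length, the difference was 0.81 after dehydration 3 h (−0.21 to 0.21), 0.53 after dehydration 1 h (−0.17 to 0.17), −0.023 after ABA 1 h, inside its range, and −0.33 after ABA 3 h, below its range of −0.19 to 0.19. An example chosen after its values were seen is AT1G48405, 18 bp behind AGO1, with 4 reads in the control, 23 after ABA 3 h and 611 after dehydration 3 h, while AGO1 had a log2 ratio of −0.26 after dehydration 3 h.

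Background reads over all low-level genes, as from genomic DNA or scaling, cannot be judged from the difference of 1.12 after dehydration 3 h, which is the pattern itself. Such reads would not depend on distance, yet among genes behind a same-strand gene, matched on control reads and length, those with a gap of up to 500 bp exceeded those beyond 1000 and up to 3000 bp by 0.807, outside the range of −0.23 to 0.23, which argues against background as the whole cause. A fixed share of reads past annotated ends would leave genes behind unchanged neighbours at the level of the others, yet behind neighbours within 0.2 log2 of the control the difference was 1.11, and 0.87 when matched (−0.26 to 0.26). A candidate explanation is transcription past the 3′ end of the upstream gene, in dehydrated seedlings more than in the others, which needs the effect to fall with distance, as the unmatched difference of 1.32 (−0.31 to 0.30) and the matched one did, while a difference of 0.26 after ABA 1 h was 0.066 when matched, inside its range. The level of the same-strand gene upstream was compared too, without matching. Low-level genes behind a gene at a CPM of at least 50 exceeded those behind a gene under 10 after dehydration. The difference was 0.92 at 3 h (−0.40 to 0.39) and 0.58 at 1 h (−0.32 to 0.32). Among genes with more than 3 control reads it was 0.43 at 3 h (−0.40 to 0.41). At 1 h it was 0.15, inside its range of −0.33 to 0.32, so a dependence on level is less clear. Each condition is 1 column sequenced as 1 pool, so whether dehydration or that pool carries the pattern cannot be separated here, and strand use in the counting is not given in the sources used here.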
